A study of Danio rerio with 6 samples.

How the data were processed

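Poly(A) RNA from tails of zebrafish (Danio rerio, strain AB) at 28 hours after fertilisation was sequenced from libraries made with an Illumina protocol, 3 libraries of wild-type (WT) embryos and 3 of sih mutants, per the labels. The authors deposited 1 table of 25745 genes with a value for each of the 6 libraries. The submitters' processing notes name the genome build Zv9 and the tools TopHat, HTSeq 0.5.3p5 and edgeR 3.0.8, with no role or order. The annotation, the strand setting, any filter and the scaling method are not given in the sources used here.

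The deposited values are a signal scale: normalised read counts, made by the authors by dividing each library's gene counts by 1 factor per library. This was tested on the values themselves. Within each library, 100% of the values above 0 were whole multiples of the value of 1 read, within a tolerance of 1e-06. The whole reads recovered in this way summed to between 21240839 and 27222955 per library, and 1 read was worth between 0.826 (WT replicate 2) and 1.43 (sih replicate 3) normalised counts. A gene with few reads has a correspondingly coarse value. The table held 372 genes without a read in any library. Gene symbols are those of the table, which leaves 37 genes unnamed and gives 167 names to more than 1 identifier. A current symbol was found for 19211 identifiers (74.6%). Where a symbol in the table now belongs to another gene, the identifier decided. No coordinates are given, since no annotation of the authors' build was used here.

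The test planned before the data were examined assumed raw counts, with limma as the fallback for normalised values. The deposited values are not raw counts, so the fallback is the main test: limma's moderated test with a mean-variance trend on log2(value + 1), two-sided, sih against WT, with all 6 libraries and no block. Genes with a mean of at least 1 in either genotype were tested (22813). Adjusted p is by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads. Count models (edgeR quasi-likelihood and exact tests, DESeq2, limma-voom) were run on the recovered reads as alternatives.

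WT and sih libraries carry the replicate numbers 1 to 3 in the labels. Whether the numbers pair the libraries was decided by a rule fixed in advance, a correlation of deviations from the genotype means above 0.1 in every pair. Over genes with a mean value of at least 50, libraries of the same number correlated at 0.932, 0.884 and 0.852 in pairs 1, 2 and 3, so the numbers pair the libraries. The bound alone would also pass WT replicate 3 with sih replicate 2 (0.136) and WT replicate 2 with sih replicate 3 (0.101). These values lie far below those of the same number. The pairing comes from these values, since the labels do not say what a number marks. The fit with the replicate number as a block (the paired fit) therefore stands beside the unblocked one. In the unblocked fit p-values measure the spread between these samples. In the paired fit they measure the spread of the differences within pairs, and limma shares variance across genes in both. The labels do not state that libraries came from separate clutches, so either spread may be technical.

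31 gene lists with 904 members, of which 53 were not found, were written before the data were examined. They cover blood, blood vessels, responses to flow and oxygen, other tissues of the tail, tissues outside it and stress. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from the residuals of the fit. These are few with 6 libraries and fewer with the block, so a list that does not pass there is not thereby unchanged. Further lists were chosen after the data had been seen and appear only among the closing observations. The rule for named genes was also fixed beforehand. It takes tnnt2a and klf2a; among called genes whose libraries do not overlap between genotypes and that reach 2 CPM, the 12 with the largest rise and the 12 with the largest fall; up to 4 called members of each list, or 2 members given as values where none is called; and the 3 most abundant called genes in each direction. No gene passed the unblocked test, so the rule was applied to the paired fit. A few further members of the lists are named that were chosen after their values were seen: gata1a, lcp1, ank1, sptb, cmyb, vegfaa, tfr1a and the copies of hbae1 and hbbe1.1.

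Alternatives covered other scalings (TMM, relative log expression, upper quartile, library totals, erythroid genes left out), a pseudocount of 0.1, no filter, a filter of 1 CPM in 3 libraries, stricter thresholds and leaving out each library or pair. On simulated counts built from these genes and libraries with 200 changed genes, the paired limma fit recovered 47.8% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 100% of those changed 4-fold, and called 6 unchanged genes among 17214 tested. The unblocked fit recovered 0 at each of these sizes. The simulation took the mean of each real pair and the spread within pairs from the data. Differences between pairs were thus built in, so the contrast between the fits does not test the pairing. The changed genes were drawn from better expressed genes, and the real test held 22813 genes. Recovery of genes with few reads was therefore not measured. In the same simulation camera called 0 of 100 lists of unchanged genes and called a list of genes raised at least 2-fold, in both fits. Simulated genes varied independently of each other, so this does not test the preset correlation for lists of genes that vary together. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.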

Results

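Tail transcriptomes were measured by mRNA sequencing in 3 wild-type (WT) libraries and 3 libraries of sih mutants, all from zebrafish embryos at 28 hours after fertilisation. sih (silent heart) is the gene of cardiac troponin T, tnnt2a, and the hearts of sih embryos do not contract. The comparison of the genotypes addresses which transcripts of the tail differ when an embryo develops without a heartbeat. WT replicates 1, 2 and 3 held 22732979, 27222955 and 27006629 reads assigned to genes, and sih replicates 1, 2 and 3 held 21240839, 26552487 and 21482799. Levels are normalised read counts, given as the mean ± SD of 3 libraries. Changes are log2 fold changes of sih against WT ± SE from limma with the replicate number as a block (the paired fit). The unblocked fit gives the same fold changes with wider errors, and its result follows the gene groups.

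Libraries of the same number resembled each other more than libraries of the same genotype did. The mean Spearman correlation was 0.986 between libraries of the same number and 0.955 between libraries of the same genotype. The first principal component, with 55.7% of the variance, set both libraries of replicate 1 apart from replicates 2 and 3, and the second, with 22.0%, set replicate 3 apart from replicate 2. Log2 changes of genes, with their SE, are therefore from the fit with the pairs as a block. The third component, with 9.1% of the variance, separated the genotypes. WT libraries lay at -57.6 to 0.69 on it and sih libraries at 18.9 to 31.2.

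**Figure D1:**
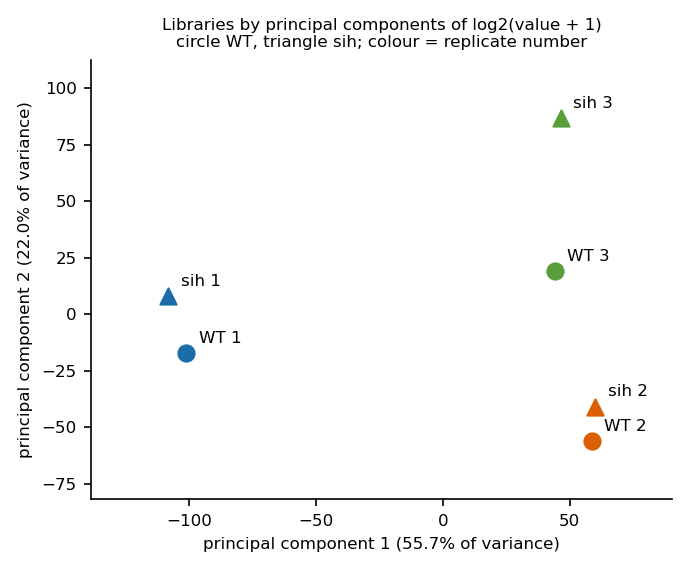
Each point is 1 library, placed by the first and second principal components of log2(value + 1), which hold 55.7% and 22.0% of the variance. Circles are WT, triangles are sih and colours are replicate numbers; both libraries of replicate 1 lie apart from the rest on the first component.

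tnnt2a (ENSDARG00000020610), the gene mutated in sih, is a heart gene and was close to the detection floor in these tails. It had 0, 9 and 4 reads in WT replicates 1, 2 and 3 and 0, 0 and 3 reads in the sih replicates, so its level in the tail does not check the labels. klf2a (ENSDARG00000042667), an endothelial transcription factor known to respond to blood flow, was at 422 ± 85.0 normalised counts in WT and 364 ± 51.7 in sih. Its change was -0.20 ± 0.13, with an adjusted p = 0.417 in the paired fit and log2 ratios of 0.08, -0.13 and -0.55 in pairs 1, 2 and 3.

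Transcripts of red blood cells rose in sih tails in every pair of libraries, and some transcripts of neutrophils fell. alas2 (ENSDARG00000038643), the enzyme that starts haem synthesis in erythroid cells, rose from 922 ± 184.5 to 4852 ± 548 normalised counts, a 5.31-fold change. npsn (ENSDARG00000010423), a protease of neutrophils, fell from 232 ± 30.5 to 42.0 ± 13.0. Genes of the vessel wall, of the tail bud and of the response to low oxygen were not called as groups in either direction, although single members of the vascular and oxygen lists changed.

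Of the 24 tested members of the erythroid list, 22 rose and 0 fell, and 22 rose when adjusted over the list alone. The median member was 4.03-fold higher, with median log2 changes of 1.98, 2.29 and 1.69 in pairs 1, 2 and 3. The embryonic alpha globin hbae3 (ENSDARG00000079305) rose from 13202 ± 2490 to 67270 ± 13588 normalised counts (2.34 ± 0.10, adjusted p = 1.06e-11). The embryonic beta globin hbbe3 (ENSDARG00000038147) rose by 2.28 ± 0.09 (adjusted p = 1.94e-12). slc4a1a (ENSDARG00000012881), the anion exchanger of the red cell membrane, rose by 2.27 ± 0.09 from 1791 ± 527 to 8594 ± 2383 normalised counts. The transcription factor gata1a (ENSDARG00000013477) rose from 87.7 ± 29.5 to 367 ± 146, a change of 2.04 ± 0.15. The table lists hbae1 under 2 identifiers, and likewise hbbe1.1. All 4 entries rose, by 2.18 to 2.34, but reads of such near-identical copies cannot be assigned to 1 of them with certainty. ank1 and sptb, which encode parts of the membrane skeleton, were the members that did not pass, at 0.04 ± 0.08 and -0.01 ± 0.10. The list took 0.209%, 0.178% and 0.203% of all reads in the WT libraries and 0.698%, 0.898% and 0.711% in the sih libraries. As a set the list was higher by camera, with an adjusted p = 2.614e-84 in the unblocked fit and 7.655e-68 in the paired fit. The call held with an estimated correlation in the unblocked fit (adjusted p = 0.01074) and not in the paired fit (adjusted p = 0.4291 with an estimated correlation). In the paired fit none of the lists written beforehand passed with an estimated correlation, a test with few degrees of freedom. The correlation estimated there for the erythroid list was 0.63, far above the preset 0.01. The camera p-values with the preset therefore overstate the evidence for genes that vary together as these do.

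Several of the steepest rises lay outside that list. rhd (ENSDARG00000002194), of the Rh blood group family, rose from 103 ± 52.3 to 564 ± 231 normalised counts (2.48 ± 0.13). GP9 (ENSDARG00000090638), a glycoprotein of thrombocytes, rose from 15.2 ± 2.67 to 86.4 ± 20.2 (2.42 ± 0.26). ucp3, a mitochondrial carrier, rose by 2.36 ± 0.20 and nmt1b, an N-myristoyltransferase, by 2.30 ± 0.14. The claudin gene cldng rose by 2.27 ± 0.32. Of 17 tested members of the haematopoietic stem and progenitor list, 3 rose and 0 fell, also when adjusted over the list alone. These were tal1 (1.33 ± 0.12), ikzf1 (1.70 ± 0.22) and lmo2 (0.75 ± 0.10), transcription factors of early blood cells. cmyb, at 0.38 ± 0.16, did not pass (adjusted p = 0.192). The list's median change was 0.05. With scaling by library totals it was -0.07, which is 0.11 above the median of all genes under that scaling. Camera gave an adjusted p = 0.04416 in the paired fit, 0.05625 in the unblocked fit and 0.6294 in the paired fit with an estimated correlation. Of 31 tested genes of oxidative stress and iron handling, 9 rose and 0 fell, also when adjusted over the list alone. They included the iron transporter slc11a2 (1.08 ± 0.09), the transferrin receptor tfr1a (1.33 ± 0.21), which is on the erythroid list as well, the ferritin chain fth1a (0.67 ± 0.09) and prdx2 (0.69 ± 0.07). Camera called that list in the unblocked fit (adjusted p = 0.001348) and the paired fit (9.272e-06), but not with an estimated correlation (adjusted p = 0.693 and 0.4291). Its median change was 0.10. With scaling by library totals it was -0.08, which is 0.10 above the median of all genes under that scaling.

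Of the 31 tested members of the macrophage and neutrophil list, 6 fell and 0 rose, and 8 fell when adjusted over the list alone. The median change was -0.64, with -0.58, -0.70 and -0.40 in pairs 1, 2 and 3. npsn fell by 2.48 ± 0.20 on the log2 scale (adjusted p = 1.74e-07). The myeloperoxidase gene mpx (ENSDARG00000019521) fell from 279 ± 94.4 to 75.4 ± 26.8 normalised counts (-1.89 ± 0.16, adjusted p = 4.19e-07), and the lysozyme gene lyz (ENSDARG00000057789) from 569 ± 139 to 206 ± 92.4 (-1.54 ± 0.15, adjusted p = 1.6e-06). The others were the cathepsin gene ctssb.1 (-1.31 ± 0.21), the granule proteoglycan gene srgn (-0.83 ± 0.17) and the leukocyte plastin gene lcp1 (-0.65 ± 0.14). Camera gave an adjusted p = 2.596e-10 for the list in the unblocked fit and 1.727e-06 in the paired fit. With an estimated correlation the adjusted p was 0.0673 and 0.4291, so neither passed. The 0.4291 of the paired fit equals that of the erythroid list and comes from a test with few degrees of freedom. Beyond the list, sele (ENSDARG00000009123), the endothelial adhesion molecule E-selectin, fell from 124 ± 25.5 to 36.4 ± 18.7 normalised counts (-1.84 ± 0.22, adjusted p = 4.76e-05), and the inflammatory caspase gene caspb fell from 81.1 ± 71.9 to 33.5 ± 32.9 (-1.32 ± 0.24).

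**Figure D2:**
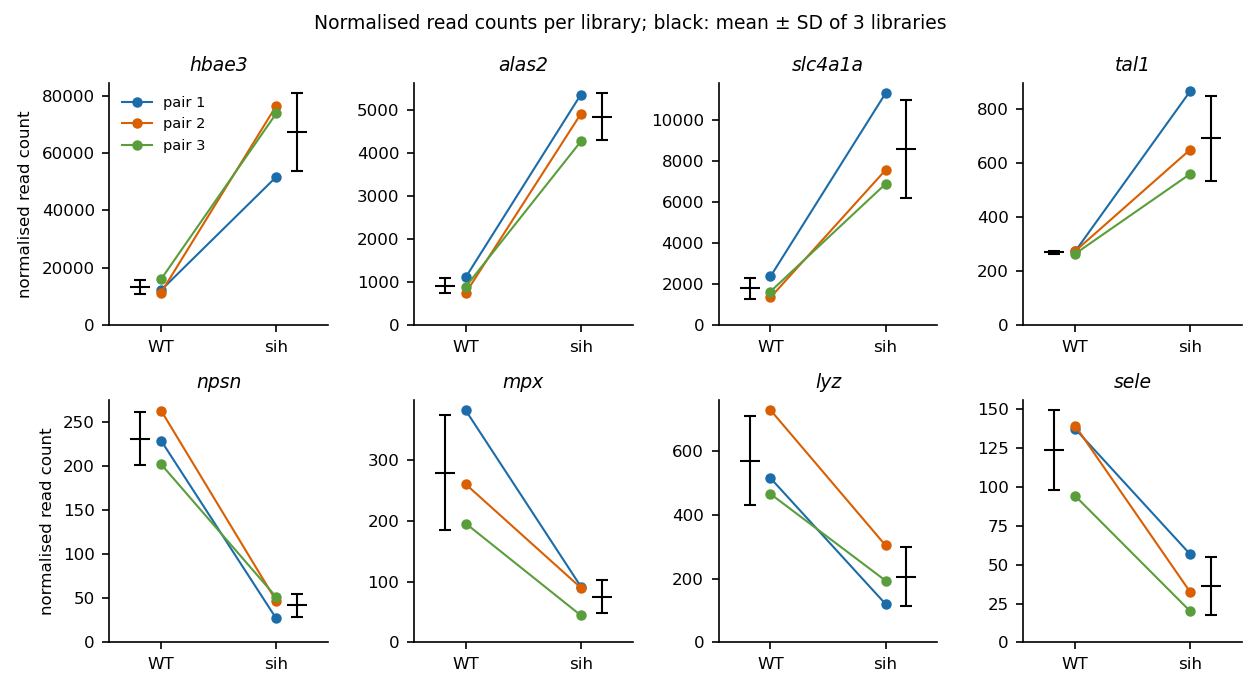
Normalised read counts (vertical axes, starting at 0) of 8 genes in WT and sih libraries; coloured lines join the libraries of a pair, and black marks are the mean ± SD of 3 libraries. hbae3, alas2, slc4a1a and tal1 are higher and npsn, mpx, lyz and sele lower in the sih library of every pair.

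Vascular lists moved little as groups. Of 30 tested pan-endothelial genes, cldn5b, a claudin of endothelial junctions, rose (0.44 ± 0.10) and the receptor gene calcrla fell (-0.72 ± 0.15), and 3 rose and 2 fell when adjusted over the list alone. Of 22 flow-responsive genes, the chemokine receptor gene cxcr4a rose (0.41 ± 0.10) and the caveolin gene cav1 fell (-0.43 ± 0.09), with 1 in each direction when adjusted over the list alone. rbpja, which encodes the DNA-binding partner of Notch, was the single arterial and Notch member of 20 that fell (-0.48 ± 0.12). mrc1a, a mannose receptor of venous and lymphatic endothelium, was the single member of 15 on its list that fell, from 708 ± 193 to 398 ± 120 normalised counts (-0.84 ± 0.15). None of 21 mural and smooth muscle genes passed. Adjusted over the list alone, the counts of the last 3 lists were the same. Camera gave adjusted p values between 0.4549 and 0.863 for these 5 lists in the paired fit. The calls of cxcr4a, cldn5b and rbpja were lost without pair 3 (adjusted p = 0.2464, 0.0519 and 0.3186).

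Of 46 tested genes of the hypoxia response, 4 rose and 2 fell, and 5 rose and 3 fell when adjusted over the list alone. The insulin-like growth factor binding protein genes igfbp1b (ENSDARG00000038666) and igfbp1a (ENSDARG00000014947) rose by 1.67 ± 0.24 and 0.95 ± 0.14, igfbp1a from 166 ± 14.7 to 322 ± 48.4 normalised counts. epas1a, which encodes a HIF2 alpha subunit, fell by 0.43 ± 0.09 on the log2 scale and the carbonic anhydrase gene ca9 fell from 57.3 ± 4.66 to 27.8 ± 11.0 normalised counts. vegfaa was at 312 ± 25.0 normalised counts in WT and 280 ± 75.1 in sih (-0.19 ± 0.13, adjusted p = 0.474). Camera did not call the list (adjusted p = 0.3375 in the paired fit). Among 24 genes of adenosine, nitric oxide, prostaglandin and renin signalling, the receptor genes adora2aa (1.24 ± 0.16) and ptger4a (1.43 ± 0.28) rose and the kinase gene prkg1a fell (-0.42 ± 0.12), with 2 in each direction when adjusted over the list alone. adora2aa went from 78.2 ± 5.87 to 187 ± 21.0 normalised counts. ca2, a carbonic anhydrase on the ionocyte list, fell from 4315 ± 869 to 2514 ± 1062 (-0.84 ± 0.10, adjusted p = 2.87e-05), and the water channel gene aqp1a.1 rose (0.52 ± 0.08). They were the called members among 21, and the same counts held when adjusted over the list alone. ca9 was not called without pair 2 (adjusted p = 0.1935), nor prkg1a without pair 3 (adjusted p = 0.4056). Among the hypoxia genes that rose, eno1a was not called without pair 2 or without pair 3 (adjusted p = 0.08167 and 0.3072). bnip3lb, also among them, was not called without pair 1 (adjusted p = 0.1862).

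Camera called 6 lists of other tissues and processes higher in the paired fit, and these calls depended on the test. Of 39 tested genes of the yolk syncytial layer, liver and gut, 11 rose and 1 fell, or 12 and 1 when adjusted over the list alone. The steepest was the elastase gene ela2 (1.98 ± 0.24), and the apolipoprotein gene apobl was the member that fell (-0.55 ± 0.13), with log2 ratios of -1.10, 0.08 and -0.64 in pairs 1, 2 and 3. Of 55 skeletal muscle genes 5 rose, among them tcap (0.84 ± 0.16) and myog (0.52 ± 0.11), and 13 rose and 2 fell when adjusted over the list alone. Of 26 glycolysis genes 3 rose, among them eno3 (0.36 ± 0.08), and 8 rose and 1 fell when adjusted over the list alone. In the epidermis and fin fold list of 32, 5 keratin-type members such as cyt1 (0.42 ± 0.09) rose and evpla fell (-0.70 ± 0.11), and 8 rose and 4 fell when adjusted over the list alone. Of 38 cell cycle genes, BUB1, aurkb and mcm7 rose by 0.36 to 0.39 and MKI67 fell (-0.49 ± 0.12), with the same counts when adjusted over the list alone. No gene of the somite and sclerotome list of 27 passed, and its members with the smallest p, twist1a and par1, were at 0.31 ± 0.10 and 0.33 ± 0.11. Camera's adjusted p in the paired fit was 5.51e-05, 0.0004887, 0.002906, 0.0198, 0.02103 and 0.03618 for these 6 lists in the order named. In the unblocked fit it was 0.009185 for the yolk list and between 0.05625 and 0.1858 for the rest. With an estimated correlation the paired adjusted p lay between 0.4291 and 0.7864, so none of these lists passed that test of low power. The adjusted p of the yolk list in the unblocked fit with an estimated correlation was 0.693. With fry in the paired fit none of the 6 lists was called (adjusted p from 0.07159 to 0.4107). Without pair 3 the calls of cyt1, eno3, BUB1, aurkb and mcm7 were lost (adjusted p from 0.08875 to 0.4546), and without pair 1 that of MKI67 (adjusted p = 0.08525). Further members lost their calls without pair 3. Those of the yolk list included apoa1a, ambpl, apoa2, apoeb, fga and fabp1b.1 (adjusted p from 0.07444 to 0.2989). Those of the glycolysis list were gapdh and eno1a (adjusted p = 0.3549 and 0.3072), so none of its 3 called genes kept the call. Those of the epidermis list were cyt1l, krt8 and KRT23 (7 of 15) (adjusted p = 0.2428, 0.3857 and 0.1481). Those of the skeletal muscle list were actc1b, pvalb4 and desma (adjusted p = 0.4828, 0.1822 and 0.3585). The list medians of 0.08 to 0.17 turned negative with scaling by library totals, which shifted the median of all genes by -0.18, and lay 0.08 to 0.16 above that median. With a trend of the changes with abundance removed, none of the 6 lists was called (adjusted p from 0.05508 to 0.8457), and camera's direction turned to lower for the skeletal muscle list (adjusted p = 0.07028) and the epidermis and fin fold list (adjusted p = 0.8457).

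**Figure D3:**
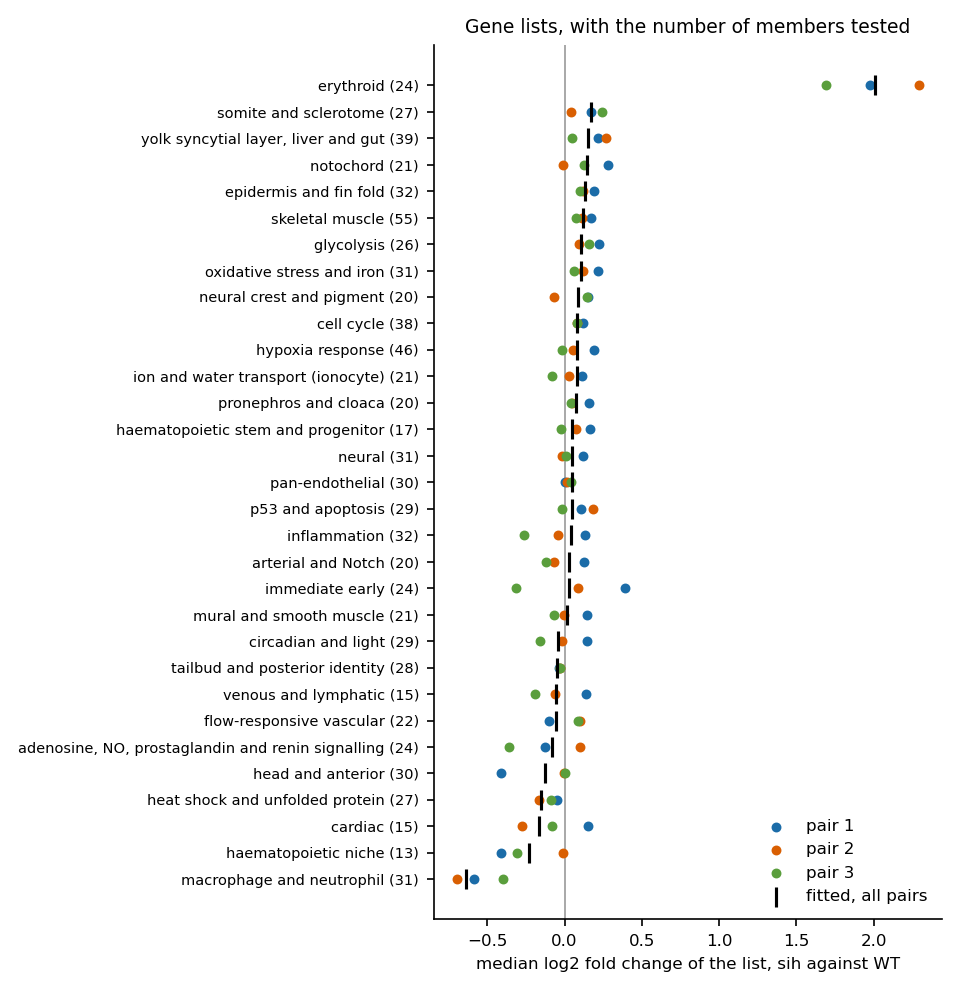
Median log2 fold change of sih against WT (horizontal axis) for each of the 31 gene lists, with the number of tested members in parentheses. Coloured points are the 3 pairs and black bars the fitted medians; the erythroid list lies at 2.01 and the macrophage and neutrophil list at -0.64.

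In the heat shock and unfolded protein list of 27, 2 rose and 4 fell, or 4 and 6 when adjusted over the list alone. Those that fell were the endoplasmic reticulum chaperone genes pdia4 (-0.60 ± 0.08), calrl (-0.48 ± 0.07), calr (-0.41 ± 0.08) and hsp90b1 (-0.40 ± 0.08). Camera's adjusted p for the list was 0.06053 in the paired fit and 0.0001317, towards lower values, with the trend with abundance removed. With an estimated correlation it was 0.5579 in the paired fit and 0.6395 in the unblocked fit. calr was not called without pair 3 (adjusted p = 0.1032). In the p53 and apoptosis list of 29, sesn2 (0.66 ± 0.11) and tp53inp1 (0.47 ± 0.11) rose and caspb fell, and 3 rose and 1 fell when adjusted over the list alone. tp53inp1 was not called without pair 2 (adjusted p = 0.05879). None of 28 tail bud and posterior identity genes passed; the smallest p were those of cyp26a1 (0.51 ± 0.16, adjusted p = 0.0702) and hoxc13a (-0.30 ± 0.10, adjusted p = 0.0990). None of the genes of the neural, neural crest, inflammation, immediate early, circadian and haematopoietic niche lists passed. The cardiac, notochord, pronephros and head lists each had 1 called member, which were actc1a and slc20a1a (higher) and loxl1 and crybb1 (lower). crybb1 was not called without pair 1 (adjusted p = 0.2511), without pair 2 (adjusted p = 0.1247) or when adjusted over the list alone, and it had 4 to 8 reads in the WT libraries and 0 or 1 in the sih libraries. actc1a was not called without pair 3 (adjusted p = 0.3239), nor loxl1 without pair 1 (adjusted p = 0.08737). Camera's adjusted p in the paired fit lay between 0.05592 and 0.863 for the 21 lists it did not call.

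The unblocked limma fit called 0 genes of 22813, with a smallest adjusted p of 0.0808 and 235 genes at an unadjusted p under 0.05. edgeR's quasi-likelihood test and limma-voom on the recovered reads also called 0, edgeR's exact test called 36 and DESeq2 called 48. The paired limma fit called 1105 genes, 632 higher and 473 lower in sih, of which 91 and 32 changed at least 2-fold, and 4284 genes had an unadjusted p under 0.05. With scaling by library totals the paired calls split into 181 higher and 2068 lower, and without pair 3 the paired fit called 506 genes, of which 419 were among the 1105. Of the genes given here as called, cxcr4a, cldn5b, myog, cyt1, eno3, BUB1, aurkb, mcm7, tp53inp1 and actc1a were not called with scaling by library totals (adjusted p from 0.06479 to 0.2161). With a pseudocount of 0.1, srgn, cxcr4a, cav1, cldn5b, rbpja, ca9, prkg1a, apobl, MKI67, aurkb, mcm7, tp53inp1, loxl1, crybb1 and actc1a were not called (adjusted p from 0.05056 to 0.1169). In both settings apoa1a, ambpl, apoa2, apoeb, fga, fabp1b.1, gapdh, eno1a, krt8, cyt1l, KRT23 (7 of 15) and bnip3lb were not called either. Their adjusted p was 0.1267 to 0.4916 with library totals and 0.05265 to 0.09177 with the pseudocount. The skeletal muscle genes actc1b, pvalb4 and desma were not called in these settings either. For them it was 0.105, 0.4097 and 0.375 with library totals and 0.09598, 0.07873 and 0.08304 with the pseudocount.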

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

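Alternatives for the paired fit, the list test with the abundance trend removed, and limma and edgeR's quasi-likelihood test with TMM, were chosen after the data had been seen, but not the block, its estimated correlation and fry. The unblocked count of 0 genes moved to 1105 (632 higher, 473 lower) with the replicate block, 48 (46 and 2) with DESeq2 and 36 (34 and 2) with edgeR's exact test, and stayed at 0 in the other settings run. The unblocked fit called 4 lists: 10 with the replicate block, 1 with an estimated correlation, 1 with fry, 8 with the filter of 1 CPM, 7 with a pseudocount of 0.1, 7 with edgeR under each of TMM, relative log expression and upper quartile, 8 with limma-voom, and 3 to 9 when leaving out 1 library (9 without WT replicate 3). The paired fit called 10 lists: 0 with an estimated correlation, 0 with fry, 4 with the abundance trend removed, and 6 with library totals in limma and in edgeR. Its 1105 genes became 334 (214 higher, 120 lower) at an adjusted p of 0.01, 123 (91 and 32) at 2-fold, 2249 (181 and 2068) with library totals, 410 (266 and 144) with a pseudocount of 0.1, 1853 (1085 and 768) with edgeR and relative log expression, and 2738 (235 and 2503) with edgeR and library totals. Leaving out a pair gave 506 to 1482 called, 256 to 744 higher and 250 to 761 lower, lowest without pair 3. Of the 1105, 653 were called with library totals, 410 with a pseudocount of 0.1 and 1087 by edgeR with TMM, all in the same direction. The excess of same-number over same-genotype correlation was 0.0306, and 0.0391 (Pearson, pseudocount 0.1), 0.0248 without a filter and 0.0566 with 1 CPM. Of 79 named genes called in the paired fit, 0 passed without the block; 19 lost the call with library totals, 24 with a pseudocount of 0.1, 19 without pair 3 and 2 of 64 with DESeq2, whose filter gave 15 no adjusted p. None of these changed sign. tnnt2a passed in no setting and was under the filters of edgeR, limma-voom and 1 CPM. The fits' own construction shows why fewer genes pass stricter thresholds; for the other changes the cause was not tested. Depth limits genes of a few reads, such as tnnt2a and runx1.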

Other observations

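The gene groups and the tests in this part were chosen after the data had been seen, except the comparison of ribosomal protein genes with genes of like abundance and the count over splits within pairs. All adjusted p are from limma or camera. Camera's adjusted p for the lists of this part is over these lists alone, apart from the lists written beforehand. Of 12 tested genes of haem synthesis and its transport, 11 rose and 0 fell, with a median log2 change of 1.33 and medians of 1.47, 1.39 and 1.13 in pairs 1, 2 and 3. Besides alas2 these included urod (1.66 ± 0.09), ppox (1.52 ± 0.11) and fech (1.55 ± 0.15). The members alas2, hmbsa, urod, fech and slc25a37 are also on the erythroid list, so the 2 lists are not independent. Camera gave an adjusted p = 4.24e-39 in the unblocked fit, and 0.002918 with an estimated correlation. The correlation estimated for this list in the paired fit was 0.42, far above the preset 0.01. Of 10 thrombocyte genes tested, GP9, gp1bb (1.63 ± 0.17), TUBB1 (1.85 ± 0.20) and nfe2 (0.65 ± 0.18) rose and 0 fell; nfe2 was not called without pair 2, with a pseudocount of 0.1 or with scaling by library totals (adjusted p = 0.3049, 0.1046 and 0.1425), among other settings. Camera called that list higher (adjusted p = 0.005179 in the paired fit, 0.1114 with an estimated correlation), with a mean change of 0.43 and a median of 0.01.

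Of 81 ribosomal protein genes, 65 rose and 1 fell, by a median of 0.36, with rplp2 at 0.52 ± 0.08. Most of these calls were lost without pair 3, such as those of rps2, rplp0 and rpl3 (adjusted p = 0.2011, 0.2482 and 0.2723). Their changes there were 0.37, 0.35 and 0.34. With scaling by library totals many of the same calls were lost, such as rpl6 and rpl21 (adjusted p = 0.2294 and 0.4284). Without pair 3 the adjusted p of rpl6 and rpl21 was 0.2428 and 0.3422. Of 49 genes that assemble ribosomes, 17 fell and 2 rose, with a median of -0.22, among them surf6 (-0.90 ± 0.17), utp3 (-0.91 ± 0.19) and nop2 (-0.75 ± 0.14), whereas ddx21 rose (0.59 ± 0.08). Of 28 chaperone genes of the endoplasmic reticulum, 9 fell and 0 rose, with a median of -0.23, led by dnajb11 (-0.94 ± 0.11) and manf (-0.70 ± 0.11). Of 13 genes of the mitochondrial genome, 5 fell and 0 rose, with a median of -0.23. Camera's adjusted p in the paired fit was 6.654e-51, 6.498e-10, 3.866e-11 and 3.546e-06 in the order named, and 0.04975, 0.04975, 0.04975 and 0.08642 with an estimated correlation. The erythroid list's 0.4291 in that test was adjusted over the lists written beforehand, so 0.04975 cannot be compared with it. These lists were chosen after the data had been seen, so no conclusion is drawn from values just under the threshold. With an estimated correlation in the unblocked fit it was 0.2906, 0.1156, 0.0747 and 0.3547. All 4 medians kept their sign under 5 other scalings, with the ribosomal protein median at 0.18 to 0.37. A scaling shifts all genes alike and the largest shift was downward, so this says little of the lists that fell. Relative to the median of all genes with library totals, the medians lay at 0.35, -0.22, -0.23 and -0.23 in the order named.

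The rise of the erythroid list was weighed first. Its median stayed between 1.83 and 2.02 under 5 other scalings, so the authors' scaling does not account for it. Nor do reads shared between globin copies: the 16 members that are not globins had a median of 1.63, and 1.34 to 1.75 by pair. The median of the 8 globins lay 0.64 above that of these 16 (0.34 to 0.86 by pair), and 0.23 above that of 9 genes picked by hand as erythroid-restricted after their values were seen (0.09 to 0.42 by pair; 8 of the 16, and rhd, which is not on the list). More erythroid cells at an unchanged programme and a changed programme per cell cannot be told apart, since the pairs lie on both sides of the 0.5 bound for the 16 and the result depends on the genes chosen; that red cells which do not circulate stay in the tail is a candidate explanation, not tested here.

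Lower neutrophil markers were weighed next. Of 11 neutrophil markers 4 fell and 0 rose, with a median of -0.83 (-1.23 to -0.74 by pair). cebpa, mmp9 and nccrp1 lay at 0.13, 0.16 and 0.04. The larger share of reads of the listed erythroid genes would change every other gene by -0.01, so dilution by those reads does not account for the fall. Other RNA of added erythroid cells is not in that share and was not measured. With scaling by library totals the median of all genes shifted by -0.18, and the neutrophil median lay at -0.84 relative to that. A shift common to all genes therefore does not account for the fall either. Neutrophil markers lay 0.27 below macrophage markers (log2 difference -0.27, -0.59 to -0.12 by pair), whose median was -0.56 but of which 1 of 13 fell (camera, lower, adjusted p = 0.05168 in the paired fit, 0.002863 in the unblocked fit and 0.01895 in paired edgeR, and with an estimated correlation 0.1757 in the paired and 0.1156 in the unblocked fit), and slc7a7, IL34 (1 of 2) and csf1ra lay at 0.39, 1.16 and 0.74, not called. IL34 (1 of 2) is also on the haematopoietic niche list and csf1ra on the neural crest and pigment list, so neither stands for macrophages alone. An equal and an unequal change of the markers of both cell types cannot be told apart, since the pairs lie on both sides of the 0.5 bound set for the test. A lower number of neutrophils that reach the tail may explain the fall of those 4 genes, and this was not tested.

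The rise of ribosomal protein genes was weighed last. The lowest median under 5 other scalings was 0.18, above 0, with library totals. It lay 0.35 above the median of all genes under that scaling. A scaling shifts all genes alike, so scaling alone does not account for the rise relative to other genes. Abundant genes lay higher in general: the 100 genes nearest in abundance had a median of 0.20. Ribosomal protein genes exceeded them by 0.16 (0.06 to 0.21 by pair), and the list was still called with the trend removed (camera, paired fit, adjusted p = 1.753e-11). A trend with abundance and a change of these genes in particular cannot be told apart, because pair-wise excesses lie on both sides of the 0.1 bound set beforehand.

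For the unblocked fit, each of the 10 splits of the 6 libraries into 3 against 3 gave 0 called genes, the real one included (highest other 0). For the paired fit, 1 of 4 splits that exchange genotypes within pairs, the real one, gave 1105 called genes, and the highest of the others gave 0. Both sets hold too few splits for a share under 0.05.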
